A study of Mus musculus with 56 samples.

How the data were processed

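Gene counts from 56 libraries of mouse barrel cortex at postnatal day 5 were analysed. They hold bound and unbound RNA from pulldowns of EGFP-tagged ribosomes in an astrocyte line (Aldh1l1), a microglial line heterozygous for a tamoxifen-inducible Cre in Cx3cr1, and a microglial line homozygous for it. Per the labels, tamoxifen (50 µg) was given to the microglial lines daily from postnatal day 1 to day 3. Whiskers of the right side were cauterised on day 4 in all 3 lines. The deposited tables hold raw read counts per Ensembl gene, 1 column per library, for 47971, 45682 and 55385 genes in the astrocyte, heterozygous and knockout lines. Of these 0, 4401 and 11618 have no count in any library. Per the submitters' processing notes, Trim Galore 0.6.4, cutadapt 2.9, FastQC 0.11.9, HISAT2 2.2.0 and featureCounts 2.0.0 were used with builds GRCm38 and mm10. Neither their settings nor the strand used in counting is stated. cDNA was made with the NuGEN Ovation V2 kit per the labels. These give the molecule as total RNA for the astrocyte and heterozygous libraries and polyA RNA for the knockout libraries. Gene symbols, positions, lengths and GC content came from the GENCODE vM21 annotation of GRCm38.

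Libraries were grouped by title. The number of a knockout library is that of the mouse, so its deprived and control libraries pair by animal. The same holds for mice 14 and 15 of the heterozygous line. Numbers in the astrocyte titles name no animal and were used as a block only in an alternative. In the knockout line the 2 libraries of a mouse correlated above 0.1, over genes after group means were removed, in 4 of 5 mice in each fraction. In the heterozygous line libraries 1 to 4 (bound) or 7 to 10 (unbound) of the control group came from pieces 14R, 15R, 21L and 21R, and those of the deprived group from 14L, 15L, 17L and 17R. Each group of the astrocyte and knockout lines held 3 female and 2 male samples per the labels, and each heterozygous group 3 female and 1 male. Expression of sex-linked genes differed from the label in 0 libraries. Every bound library correlated best with the unbound library of its own piece (10 of 10, 8 of 8 and 10 of 10 in the 3 lines).

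Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr on the groups in the fit, a quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested. The threshold was 0.05. All tests were two-sided. Deprived and control libraries were compared within each line and fraction with only these groups in the fit and no covariate. Bound and unbound RNA, and the difference of the deprivation effect between them, were tested with all 4 groups of a line in the fit. The deprivation effect and the enrichment were compared between genotypes over the 45681 genes present in both microglial tables, as was the level in bound RNA. CPM (counts scaled to library size) used TMM library sizes and log2 values a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also adjusted over the list alone. The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise.

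Named genes were, where at least 20 passed, the 10 higher and 10 lower with the largest change and a mean log2 CPM of at least 3. Otherwise they were all that passed plus up to 10 per direction by smallest p. To these were added up to 4 members by smallest p of each list that was called or had a called member, and a fixed set of genes of the fractalkine, Wnt, astrocyte and microglia systems. The 5 largest per direction were added for enrichment, and up to 5 per direction for interactions. Predicted genes and genes without a symbol were left out, and a few genes that met the rule are not named here. Among the genes named, Aldh1l1, Atf5, Axin2, B3galt2, Bahcc1, Csf1r, Cx3cr1, Cxxc4, Fgfr1, Id4, Il1b, Lef1, Nefl, Neurod1, P2ry12, Pla2g4e, Rtn4, Rtp4, Shank1, Slc1a2, Sowaha, Tbc1d5, Wnt5a, Wnt7b and Zbtb20 overlap another annotated gene. Their counts are uncertain to that extent.

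Each comparison was repeated with DESeq2 size factors, without the filter on low counts, with the DESeq2 1.42.0 Wald test, and with limma-voom and sample weights. It was also repeated with sex or the replicate number as a term, with all 4 groups in the fit, and without each library in turn. For the heterozygous line the groups were also formed by the side letter of the library name, and libraries 17R and 21L were left out. After seeing the data, fits were added that summed the libraries of mice 17 and 21, used mice 14 and 15 alone, or left out knockout mice 7 and 18 or astrocyte control pieces 3 and 4. The alternatives for the genotype difference in bound RNA were added then too, among them a fit that summed the libraries of each mouse. The test was checked on simulated counts with 200 changed genes. At a 2-fold change it recovered 65% and 91% of them in the bound and unbound libraries of the astrocyte line, 76% and 79% in the heterozygous line, and 74% and 91% in the knockout line, with 7 to 17 false calls. At a 1.5-fold change it recovered 35% in the bound libraries of the knockout line and 53% in those of the heterozygous line. For the difference between genotypes it recovered 18%, and 56% at 2-fold.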

Results

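RNA was sequenced from barrel cortex, the area of the cerebral cortex that maps the whiskers, of mice at postnatal day 5. The whiskers of the right side had been cauterised 24 h earlier, on postnatal day 4. Ribosomes of 1 cell type carried the protein L10a fused to EGFP and were pulled down with an antibody to the tag (translating ribosome affinity purification). Both the bound RNA and the RNA left unbound were sequenced. The tag was in astrocytes in an Aldh1l1 line, and in microglia in a pair of lines in which tamoxifen-activated Cre recombinase, written into the Cx3cr1 gene, had switched it on. In the heterozygous line 1 copy of Cx3cr1 carried the insertion, and in the knockout line both copies did. The 56 libraries formed 12 groups. There were 5 deprived and 5 control libraries in each fraction of the astrocyte and knockout lines, and 4 and 4 in each fraction of the heterozygous line. Library totals were 10.9 to 28.6 M counts (M, mega) in bound and 10.1 to 24.3 M in unbound libraries of the astrocyte line. They were 39.9 to 49.7 and 32.8 to 50.7 M in the heterozygous line, and 35.8 to 53.9 and 34.6 to 56.7 M in the knockout line. Changes are log2 fold changes ± standard error, positive where deprived cortex was higher, and libraries are named by group and number. The p-values measure the spread between libraries, since the astrocyte labels do not name animals and the microglial libraries of both lines came from fewer animals than libraries.

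Cx3cr1, the fractalkine receptor of microglia and the gene carrying the insertion (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, GRCm38), was read first to check the genotypes. Bound libraries held 9.57 ± 2.16 CPM (counts scaled to library size; SD, n = 8, range 6.56 to 12.6) in the heterozygous line. They held 0.786 ± 0.229 CPM (SD, n = 10, range 0.338 to 1.26) in the knockout line. The knockout level was lower by a log2 difference of -3.56 ± 0.16 (edgeR, adjusted p = 1.1e-11), with the lowest heterozygous library above the highest knockout library. Unbound libraries held 1.46 ± 0.343 CPM (SD, n = 8) in the heterozygous and 0.0885 ± 0.0558 (SD, n = 10, 2 to 8 counts per library) in the knockout line. The astrocyte line, where Cx3cr1 was intact, held 3.11 ± 0.791 CPM bound and 5.81 ± 1.13 unbound (SD, n = 10 each). The labels do not say which part of the gene the insertion removes, and the antisense gene Gm33858 overlaps it, so the remaining knockout counts are not assigned to either.

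**Figure D1:**
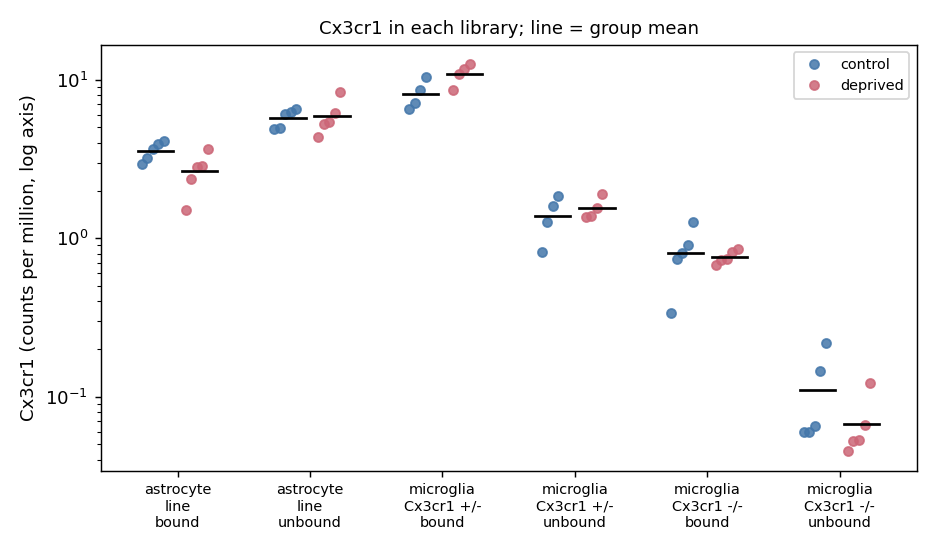
Cx3cr1 in CPM (log axis) in each library by line, fraction and whisker treatment, with points for libraries and a line for each group mean. Bound libraries range from 6.56 to 12.6 in the heterozygous line and from 0.338 to 1.26 in the knockout line.

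Between the same bound libraries, genes of the interferon response, which cells switch on when they sense virus or interferon, were lower in the knockout line. Of these, 16 of 16 measured members lay below 0, with a median of -0.63 (camera adjusted p = 3.7e-40, and adjusted p = 0.0030 with an estimated correlation). Isg15, a ubiquitin-like modifier (-0.97 ± 0.14, adjusted p = 0.0040), Oasl2 (-0.89 ± 0.14), Rtp4 (-0.65 ± 0.11) and Oas1a (-0.84 ± 0.15) passed over all genes. Of the members, 15 passed adjusted over the list alone. The gap was not particular to bound RNA: unbound libraries held Oasl2 at 165 CPM in the heterozygous and 94.5 in the knockout line, and Isg15 at 9.29 and 5.95. Both microglial lines lay far above the astrocyte line. That line had intact Cx3cr1, has no tamoxifen in its labels and came from another count table, so this gap cannot be assigned to any of these. Bound Oasl2 stood at 185, 96.2 and 1.94 CPM in the heterozygous, knockout and astrocyte lines, and Isg15 at 5.73, 2.81 and 0.382. The zinc finger gene Zfp457 (2.24 ± 0.26) was higher in the knockout line. Tcf7l2, a transcription factor of Wnt signalling, passed on the average of control and deprived libraries (1.22 ± 0.22, adjusted p = 0.028). Its levels were 94.2 CPM in control and 13.4 in deprived libraries of the knockout line, against 15.0 and 15.9 in the heterozygous line, so the difference came from the knockout control libraries. In all 11 of 19601 genes passed, 4 higher and 7 lower in the knockout line (edgeR, 1465 at unadjusted p under 0.05, 71 with DESeq2, 27 with limma-voom). The microglia markers had a median of -0.31, with all 22 lower. Camera gave the microglia markers adjusted p = 1.9e-21, and adjusted p = 0.11 with an estimated correlation. Other lists moved with them. Lower in the knockout line were also cell cycle genes (median -0.23, adjusted p = 2.5e-10), cytosolic ribosomal proteins (-0.09, 1.6e-06), microglial activation genes (-0.16, 6.6e-04) and actin linkers (-0.06, 0.0028), with all 19 cell cycle genes and 27 of 28 ribosomal proteins below 0, and the fractalkine list that holds Cx3cr1 (adjusted p = 4.1e-10). Higher were mitochondrially encoded genes (median 0.27, adjusted p = 3.2e-08), endothelial markers (0.23, 1.6e-04), Wnt receptors (0.12, 0.0023), glutamate and potassium handling (0.10, 0.0029), Wnt antagonists (0.19, 0.0052), astrocyte markers (0.08, 0.032) and synaptogenic and matrix factors (0.09, 0.037), with all 11 mitochondrial genes above 0. With an estimated correlation the lower lists had adjusted p = 0.17, 0.44, 0.37, 0.11 and 0.0030, and the higher ones 0.13, 0.17, 0.11, 0.31, 0.12, 0.50 and 0.48. Genotype coincided with the count table and with the labelled RNA type, so a genotype difference and a batch difference cannot be told apart here. The count was 7 without heterozygous control 3 or heterozygous deprived 4, 21 without heterozygous control 1, 31 without heterozygous deprived 1, 20 without knockout control 12 and 17 without knockout control 18. The calls of Oas1a, Rtp4 and Tcf7l2 were lost in 6, 3 and 9 of the 18 fits that left out 1 library. Those of Cx3cr1, Isg15, Oasl2 and Zfp457 were kept in all 18. Each mouse gave 2 of these libraries, and with them summed (4 heterozygous and 5 knockout mice, a fit added after the data were seen) 1 gene passed, Cx3cr1 (-3.59 ± 0.18, adjusted p = 8.6e-07). In that fit Isg15 had adjusted p = 0.30, Oasl2, Zfp457 and Tcf7l2 each adjusted p = 0.23, and Rtp4 and Oas1a each adjusted p = 0.78. The interferon genes kept a median of -0.71 with all 16 below 0, at adjusted p = 4.3e-34, and adjusted p = 0.067 with an estimated correlation.

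The bound and unbound fractions were compared in each line to see which cell type the pulldown had drawn from. In the astrocyte line (n = 10 libraries per fraction) the bound fraction was enriched in Aldh1l1, the folate enzyme whose promoter drove the tag (1.93 ± 0.06), and in Gfap, an intermediate filament protein of astrocytes (2.59 ± 0.09). The glutamate transporters Slc1a3 (1.12 ± 0.05) and Slc1a2 (0.83 ± 0.05), and the gap junction protein Gja1 (1.06 ± 0.08) were enriched too. Of the 23 astrocyte markers, 21 passed as enriched over all genes and 21 adjusted over the list alone, with a median of 1.07. Camera gave these markers adjusted p = 1.3e-28, and adjusted p = 0.0049 with an estimated correlation. Microglia markers lay below 0 with a median of -0.51, among them P2ry12 (-1.47 ± 0.11) and Cx3cr1 (-0.89 ± 0.14).

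In the heterozygous line (n = 8 per fraction) the bound fraction was enriched in microglial genes, among them the complement component C1qc (3.32 ± 0.11), the growth factor receptor Csf1r (2.81 ± 0.08), Tmem119 (2.78 ± 0.19), Cx3cr1 (2.65 ± 0.14) and the purine receptor P2ry12 (2.56 ± 0.15). All 22 measured microglia markers passed as enriched, with a median of 2.79. Camera gave this list adjusted p = 2.1e-32, and adjusted p = 0.047 with an estimated correlation. The knockout line (n = 10 per fraction) gave a median of 2.72 for the same 22 markers (adjusted p = 1.9e-13, and adjusted p = 0.47 with an estimated correlation). Cx3cr1 stood at 3.13 ± 0.28 and Csf1r at 2.72 ± 0.22 there. Astrocyte markers had medians of -0.50 and -0.48 in these lines. Gfap was enriched in the heterozygous line (1.16 ± 0.09), and Aldh1l1 was not (-0.15).

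**Figure D2:**
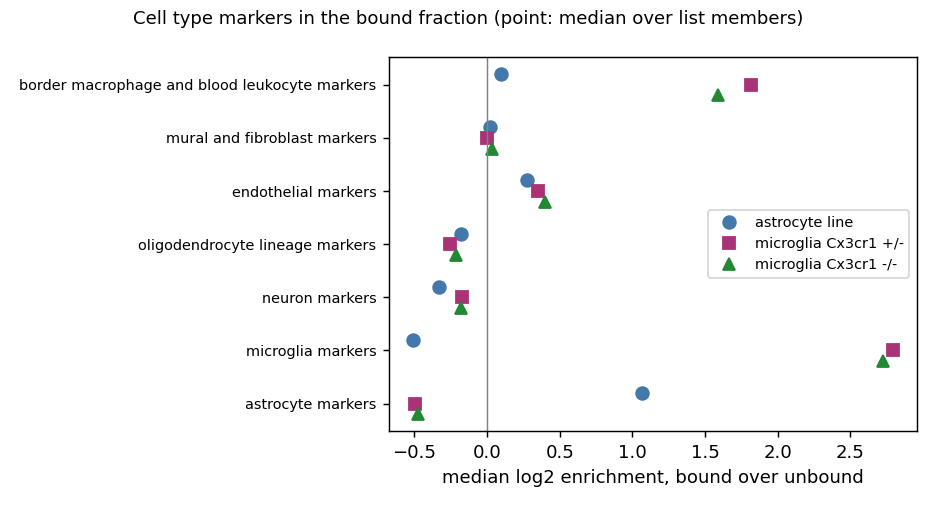
Median log2 enrichment of bound over unbound RNA for the members of 7 marker lists in each of the 3 lines, with 1 symbol per line. Astrocyte markers lie at 1.07 in the astrocyte line, and microglia markers at 2.79 and 2.72 in the heterozygous and knockout lines.

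Among the most enriched genes were some shared across lines that are not cell type markers. Tnrc18, which encodes a nuclear protein, stood at 6.82 ± 0.14 in the heterozygous and 6.50 ± 0.16 in the knockout line. Others were Yeats2 (6.95 ± 0.07 in the astrocyte line, 6.48 and 6.34 in the others) and Bahcc1 (6.05 ± 0.11, 6.56 and 6.27), which encode nuclear proteins too. The mitochondrial ribosomal RNAs mt-Rnr1 (-1.32 ± 0.11, -4.28 and -4.30 in the astrocyte, heterozygous and knockout lines) and mt-Rnr2 (-1.36, -3.93 and -3.96) were depleted. They made up 1.83 ± 0.295% of counts in bound and 4.72 ± 0.934% in unbound libraries of the astrocyte line (SD, n = 10 each). The shares were 1.68 ± 0.183% and 24.3 ± 2.46% in the heterozygous line (SD, n = 8 each), and 1.91 ± 0.601% and 26.8 ± 2.55% in the knockout line (SD, n = 10 each). Neuron markers had medians of -0.33, -0.17 and -0.18 (means of 0.16 in both microglial lines). The neurofilament gene Nefl was enriched in all 3 lines (4.21, 4.59 and 4.41). Over all genes 5778 were enriched and 5060 depleted of 18324 in the astrocyte line. The numbers were 6127 and 5942 of 19275 in the heterozygous line, and 6211 and 5976 of 19681 in the knockout line.

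Deprived and control cortex were compared in the astrocyte line to ask what whisker loss does to astrocytes within 1 day. No gene passed in the bound fraction (n = 5 per group). Gfap stood at 0.28 ± 0.10, Aldh1l1 at 0.13 ± 0.08, Slc1a2 at 0.11 ± 0.09 and Gja1 at -0.12 ± 0.09. The Wnt ligands, secreted growth factors that the series title names as the signalling route, stood at 0.05 ± 0.15 for Wnt5a, 0.18 ± 0.10 for Wnt7b, -0.10 ± 0.15 for Wnt7a and 0.19 ± 0.15 for Wnt4. Wls, which carries them to the cell surface, stood at -0.21 ± 0.17 and the Wnt target Axin2 at 0.09 ± 0.11. The smallest p-values belonged to Nr4a2, an activity-induced nuclear receptor (0.41 ± 0.08), Bcap29 (-0.55 ± 0.12), Rtn4, an inhibitor of neurite growth (-0.32 ± 0.07), and Bcl2l11 (0.45 ± 0.10). Also among them were the guidance genes Ntn1 (-0.50 ± 0.13) and Robo2 (-0.34 ± 0.09), and the transcription factors Zbtb20 (0.48 ± 0.11), Atf5 (0.53 ± 0.13) and Tcf4 (0.31 ± 0.08). All of these had adjusted p = 0.67. edgeR called 0 of 17685 genes, with 1067 at unadjusted p under 0.05, against 7 with DESeq2 and 0 with limma-voom.

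As a group, immediate early genes, which neural activity induces within minutes, rose in astrocyte-bound RNA of deprived cortex, with 14 of 19 members above 0, and a median of 0.13. Of these, 3 passed the test adjusted over the list alone but 0 over all genes. Camera gave these genes adjusted p = 0.0025, and adjusted p = 0.51 with an estimated correlation. Engulfment and complement genes fell with a median of -0.11 (adjusted p = 0.010, and adjusted p = 0.82 with an estimated correlation). Stress and heat shock genes fell with a median of -0.13 (adjusted p = 0.010, and adjusted p = 0.51 with an estimated correlation), and cytosolic ribosomal proteins with a median of -0.08 (adjusted p = 0.0068, and adjusted p = 0.82 with an estimated correlation).

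The unbound fraction of the astrocyte line (n = 5 per group) also gave no gene. Lhx2, a cortical transcription factor, stood at 0.23 ± 0.05 and Dab1, the reelin adaptor, at 0.18 ± 0.04. St18 stood at 0.60 ± 0.14, Siah3 at 0.26 ± 0.05 and Fign at -1.41 ± 0.34 among the smallest p-values, each at adjusted p = 0.58. Gfap stood at 0.13 ± 0.12 and Wnt5a at 0.10 ± 0.11. All 13 mitochondrially encoded genes lay below 0 with a median of -0.18. Camera gave mitochondrial genes adjusted p = 1.7e-04, and adjusted p = 0.52 with an estimated correlation. Astrocyte synaptogenic and matrix factors (median -0.11, adjusted p = 1.8e-04), engulfment and complement genes (-0.10, 1.8e-04) and Wnt receptors (-0.10, 0.016) fell as groups, each without a called member. They had adjusted p = 0.50, adjusted p = 0.43 and adjusted p = 0.43 with an estimated correlation. Oligodendrocyte lineage markers (median -0.06, adjusted p = 0.0038), endothelial markers (-0.15, 0.0038) and genes of glutamate and potassium handling (-0.08, 0.0046) fell too, also without a called member (adjusted p = 0.43, 0.52 and 0.52 with an estimated correlation). edgeR called 0 of 16846 genes, with 1043 at unadjusted p under 0.05, and DESeq2 and limma-voom also gave 0 and 0. The difference between the effects in bound and unbound RNA likewise gave 0 genes with edgeR (546 at unadjusted p under 0.05), DESeq2 and limma-voom. As groups, mitochondrially encoded genes (median 0.44, adjusted p = 0.0036), cytosolic ribosomal proteins (-0.10, 7.7e-04) and stress and heat shock genes (-0.09, 0.027) differed between the fractions (adjusted p = 0.98, 0.98 and 0.93 with an estimated correlation).

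Deprived and control bound libraries of the heterozygous line were compared (n = 4 per group, by title). The question was how microglia with a working Cx3cr1 allele respond to whisker loss. Il16, a cytokine that binds CD4 (ENSMUSG00000001741, chromosome 7, 83642825 to 83745726), rose by 2.29 ± 0.20 (adjusted p = 7.4e-05). The zinc finger transcription factors of midline development Zic1 (2.08 ± 0.19) and Zic4 (2.30 ± 0.24) rose, as did the thyroid hormone binding protein Crym (2.02 ± 0.19), the semaphorin receptor Nrp2 (2.24 ± 0.26) and the guidance ligand Slit3 (1.47 ± 0.19). Also higher were the zinc finger gene St18 (1.56 ± 0.17), Sertm1 (1.39 ± 0.14), and the interferon-inducible Ifi203 (1.56 ± 0.18) and Mndal (1.64 ± 0.23). Genes that fell most were the transcriptional regulator Mn1 (-1.01 ± 0.15), Ylpm1 (-0.79 ± 0.14), the chloride channel family member Clic5 (-0.76 ± 0.16), and the integrin Itgb3 (-0.76 ± 0.11). The homeobox gene Mkx (-0.74 ± 0.12), D10Wsu102e (-0.74 ± 0.17, call lost without deprived 2), Rorb, a nuclear receptor of layer 4 neurons (-0.72 ± 0.11), the potassium channel Kcnh5 (-0.72 ± 0.13) and the noncoding RNA Cerox1 (-0.72 ± 0.13) fell next. Over all genes 1850 of 18001 passed in this grouping by title, 993 higher and 857 lower, 255 of them by more than 2-fold. In the grouping by side letter, given below, 0 passed. Il16, Zic1, Zic4, Ifi203, Mndal, Mkx, D10Wsu102e and Cerox1 overlap other genes. The strand used in counting is not stated, so their reads can belong to a neighbour.

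**Figure D3:**
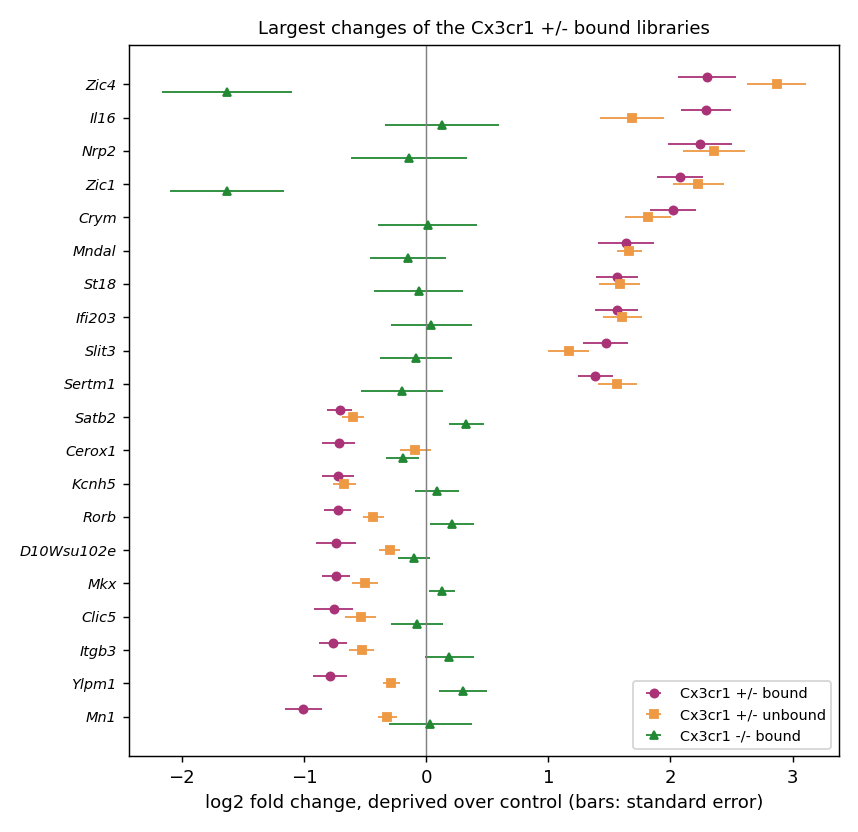
Log2 fold change ± SE of deprived against control cortex for the 20 genes with the largest changes in bound RNA of the heterozygous line, shown also for its unbound RNA and for bound RNA of the knockout line. Il16 lies at 2.29 and Mn1 at -1.01 in bound RNA of the heterozygous line.

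Microglial genes rose as a group in bound RNA of the heterozygous line. All 22 markers lay above 0 with a median of 0.51, and 11 passed over all genes and 18 adjusted over the list alone. They included the actin-binding protein Aif1 (0.98 ± 0.15), Csf1r (0.54 ± 0.10), Tmem119 (0.61 ± 0.18, adjusted p = 0.041) and P2ry12 (0.54 ± 0.16, adjusted p = 0.049). The list had adjusted p = 1.2e-10, and adjusted p = 0.27 with an estimated correlation. The transcript of the tag (GFPgene), chosen after its values were seen, rose by 0.53 ± 0.14 (adjusted p = 0.028) in these libraries. That is about the size of the marker median, and a rise of microglial genes beyond that of the tag was not tested. Cx3cr1 stood at 0.41 ± 0.15 (adjusted p = 0.099) and passed only without control 1, among the fits that left out 1 library. The call of Tmem119 held, in those fits, only without control 2, and that of P2ry12 only without control 1 or 2.

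Interferon response genes rose with all 16 members above 0, a median of 0.60, and 9 called and 14 adjusted over the list alone. They included Ifi27l2a (0.92 ± 0.15), Ifit3 (0.93 ± 0.19) and the viral entry inhibitor Ifitm3 (0.89 ± 0.15). Camera gave the interferon response adjusted p = 9.0e-10, and adjusted p = 0.27 with an estimated correlation. Inflammatory cytokine and NF-kB genes rose with all 14 above 0, a median of 0.68, 4 called and 9 adjusted over the list alone, with the cytokine Il1b at 2.39 ± 0.47. Camera gave the cytokine list adjusted p = 1.4e-05, and adjusted p = 0.29 with an estimated correlation. Engulfment and complement genes rose with a median of 0.33 and 8 of 28 called, 14 higher and 1 lower adjusted over the list alone. Complement C3 stood at 1.15 ± 0.22 and C1qb at 0.59 ± 0.12. Camera gave engulfment genes adjusted p = 3.3e-06, and adjusted p = 0.23 with an estimated correlation. Microglial activation genes rose with a median of 0.44 and 2 called, the lipase Lpl at 0.76 ± 0.11. Camera gave activation genes adjusted p = 1.4e-04, and adjusted p = 0.29 with an estimated correlation. Markers of border macrophages and blood leukocytes rose with all 11 above 0, a median of 1.33 and 6 called, 8 adjusted over the list alone, with Ms4a7 at 1.31 ± 0.30. Camera gave the macrophage markers adjusted p = 3.0e-07, and adjusted p = 0.27 with an estimated correlation. Cell cycle genes also rose, with a median of 0.26 and 5 of 19 called. Camera gave cell cycle genes adjusted p = 5.3e-04, and adjusted p = 0.29 with an estimated correlation.

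Genes of other cell types moved in the same bound libraries. Reactive astrocyte genes rose with 15 of 17 above 0 and a median of 0.74, 9 called and 10 adjusted over the list alone. Gfap stood at 0.74 ± 0.10 (adjusted p = 0.0012) and the complement inhibitor Serping1 at 1.84 ± 0.28. Camera gave reactive astrocyte genes adjusted p = 6.3e-08, and adjusted p = 0.11 with an estimated correlation. Astrocyte markers rose with a median of 0.28 and 6 of 23 called, 13 adjusted over the list alone. The gap junction proteins Gjb6 (1.32 ± 0.30) and Gja1 (0.51 ± 0.12) and Slc1a3 (0.44 ± 0.10) rose, while Slc1a2 stood at -0.04 ± 0.07 and Aldh1l1 at 0.32 ± 0.12. Camera gave astrocyte markers adjusted p = 1.4e-05, and adjusted p = 0.11 with an estimated correlation. Neuron markers fell with 16 of 20 below 0 and a median of -0.22, 5 lower and 1 higher called. They included Rbfox3, the NeuN antigen (-0.46 ± 0.08), the cortical transcription factor Tbr1 (-0.37 ± 0.07) and, higher, the GABA-making enzyme Gad1 (0.54 ± 0.09). Camera gave neuron markers adjusted p = 0.0017, and adjusted p = 0.23 with an estimated correlation. Synaptic genes fell with 20 of 25 below 0 and a median of -0.21, 10 lower and 3 higher called. Examples were the release protein Stx1a (-0.46 ± 0.09), the scaffold Shank1 (-0.50 ± 0.11) and, higher, the glutamate receptor Gria1 (0.63 ± 0.12). Camera gave synaptic genes adjusted p = 5.3e-04, and adjusted p = 0.29 with an estimated correlation. Oligodendrocyte lineage markers fell with a median of -0.12 and 2 of 14 called (adjusted p = 0.040, and adjusted p = 0.36 with an estimated correlation). Cytosolic ribosomal proteins rose with 27 of 28 above 0, a median of 0.15 and 3 called (adjusted p = 4.3e-04, and adjusted p = 0.48 with an estimated correlation). Genes of the fractalkine axis rose with a median of 0.32 (adjusted p = 0.024, and adjusted p = 0.23 with an estimated correlation). Without deprived 2 the calls of Gja1 and Slc1a3 were lost.

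Among genes of the Wnt pathway, the ligand Wnt5a rose by 0.55 ± 0.12 (adjusted p = 0.012) in bound RNA of the heterozygous line. The receptors Fzd1 (1.12 ± 0.17) and Fzd7 (1.04 ± 0.16) rose, and Fzd3 fell (-0.43 ± 0.10). Wnt4 (0.43 ± 0.20), Wls (0.43 ± 0.19) and the Wnt effector Lef1 (0.58 ± 0.19, adjusted p = 0.063) did not pass, though each did without control 3. Wnt7a (0.05 ± 0.12), Wnt7b (-0.06 ± 0.13), Axin2 (0.13 ± 0.10), Cx3cl1, the neuronal ligand of Cx3cr1 (0.10 ± 0.09), and Adam10, the protease that sheds it (0.05 ± 0.07), did not pass. The lists of Wnt ligands (median 0.05), Wnt receptors (-0.01, though the mean was 0.22) and canonical Wnt targets (0.13) were not called (adjusted p = 0.45, 0.098 and 0.060).

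Genes typical of neighbouring brain regions moved with the heterozygous groups. The lists were written after this result was seen and hold some of its called genes, so their medians describe the groups and no test is given. In bound RNA the medians were 0.63 for the hippocampal list, with the granule cell gene Prox1 among its members, and 1.19 for the septum and midline list, which holds Zic1 and Zic4. They were 0.39 for the list of non-primary cortical areas, which holds Crym, 0.26 for the thalamic list and -0.06 for the striatal list (mean 0.04). Unbound RNA gave medians of 0.86, 1.35, 0.22 and 0.15 for the same first 4 lists.

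The labels of the heterozygous line conflict for a pair of mice, and a grouping by title gives the result above while a grouping by side letter does not. Library 17R is titled deprived and library 21L control, whereas every other microglial library has L for deprived and R for control. By title, mouse 17 gave both of its pieces to the deprived group and mouse 21 both to the control group. Per the labels the whiskers of the right side were cauterised, a lesion that should leave each mouse a deprived and a control piece. The titles of mice 17 and 21 conflict with that surgery, whereas the grouping by side letter does not. The labels do not say whether the title or the library name is wrong, so the counts by title depend on this. Grouped by side letter, 0 genes passed in bound RNA with edgeR (810 at unadjusted p under 0.05) and 0 in unbound RNA (956). With the mouse as a replicate block as well, 0 (1232) and 0 (1078) passed. Mice 14 and 15 alone, whose labels do not conflict, gave 1270 genes in bound and 808 in unbound RNA with the mouse as a replicate block (2 libraries per group, a fit added after the data were seen). Of these, 855 and 428 were among the 1850 and 678 by title. Leaving out 17R and 21L left 741 genes in bound RNA, 685 of them among the 1850. Summing the libraries of each of the mice 17 and 21 left 951, of which 928 were shared. Leaving out 1 library moved the bound count to 1068 without control 4 and to 938 without deprived 2.

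Unbound RNA of the heterozygous line, from all cells of the piece (n = 4 per group), changed in many of the same genes. Zic4 (2.87 ± 0.24), Zic1 (2.23 ± 0.21), Nrp2 (2.36 ± 0.26) and Crym (1.82 ± 0.19) rose again, as did Mndal (1.66 ± 0.10, adjusted p = 3.5e-06), St18 (1.58 ± 0.17) and Sertm1 (1.57 ± 0.16). Tnfaip8l3 (1.52 ± 0.11), the growth factor receptor Fgfr1 (1.39 ± 0.15) and the neuronal transcription factor Neurod1 (1.55 ± 0.28) rose as well. The T cell receptor gene Trbc2 (-0.81 ± 0.12), Kcnh5 (-0.67 ± 0.09), the activity-regulated factor Mef2c (-0.58 ± 0.09) and Klhl1 (-0.56 ± 0.07) were among those that fell most. Pdzd2 (-0.54 ± 0.07), the clock gene Npas2 (-0.54 ± 0.08), Tbc1d5 (-0.53 ± 0.09) and Pla2g4e (-0.53 ± 0.09) fell, as did Clic5 (-0.54 ± 0.12), whose call was lost without control 8 or 9 or deprived 7, 8 or 10. In all 678 of 18073 genes passed, 488 higher and 190 lower, 195 by more than 2-fold (1176 with DESeq2). Of the genes called in bound RNA, 408 passed in unbound RNA in the same direction. These were 289 higher and 119 lower, and 0 passed in the opposite direction. Across genes the changes in the fractions had r = 0.61. Both fractions came from the same pieces, so neither value is an independent repeat.

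Wnt genes rose as groups in unbound RNA of the heterozygous line. The ligands Wnt5a (0.70 ± 0.12, adjusted p = 0.0053) and Wnt2 (2.34 ± 0.46, adjusted p = 0.012), the receptors Fzd1 (1.24 ± 0.12) and Fzd7 (1.36 ± 0.18) and Lef1 (0.93 ± 0.22, adjusted p = 0.034) rose. Wnt4 (0.39 ± 0.14) and Axin2 (0.22 ± 0.08) did not pass. Wnt ligands rose with a median of 0.20 and 2 of 9 called, 3 adjusted over the list alone. Camera gave Wnt ligands adjusted p = 0.0055, and adjusted p = 0.28 with an estimated correlation. Canonical Wnt targets rose with a median of 0.22 and 3 of 18 called. Camera gave the targets adjusted p = 7.6e-04, and adjusted p = 0.28 with an estimated correlation. Wnt receptors rose with a median of 0.13 (adjusted p = 0.0031, and adjusted p = 0.23 with an estimated correlation). Wnt antagonists rose with a median of 0.27 (adjusted p = 0.015, and adjusted p = 0.32 with an estimated correlation). Among the fits that left out 1 library, the call of Lef1 held only without control 7 or 10, and that of Wnt2 was lost without deprived 8.

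Glial genes rose in unbound RNA as well. Astrocyte markers had a median of 0.26, with 22 of 23 above 0, 4 called and 16 adjusted over the list alone. Gfap (0.71 ± 0.12) and Slc1a2 (0.29 ± 0.07) rose, while Slc1a3 (0.23 ± 0.07), Gja1 (0.41 ± 0.13) and Aldh1l1 (0.04 ± 0.10) did not pass. Camera gave the astrocyte markers adjusted p = 6.4e-08, and adjusted p = 0.23 with an estimated correlation. Reactive astrocyte genes had a median of 0.67, with the filament protein Vim at 0.52 ± 0.08 and Serpina3n at 1.36 ± 0.27. Camera gave the reactive genes adjusted p = 5.9e-10, and adjusted p = 0.15 with an estimated correlation. Microglia markers had a median of 0.21 (adjusted p = 0.0031, and adjusted p = 0.42 with an estimated correlation). Csf1r stood at 0.37 ± 0.14, P2ry12 at 0.54 ± 0.22, Tmem119 at 0.67 ± 0.34 and Cx3cr1 at 0.20 ± 0.24, none of which passed. Interferon response genes had a median of 0.43 with all 16 above 0. Camera gave the interferon genes adjusted p = 1.5e-05, and adjusted p = 0.39 with an estimated correlation. Also called were border macrophage and leukocyte markers (median 1.16, adjusted p = 8.1e-07), genes of glutamate and potassium handling (0.26, 3.4e-04), microglial activation (0.21, 6.4e-04), cytokines and NF-kB (0.48, 0.0024) and engulfment (0.15, 0.019), all higher, and neuron markers (-0.07, 0.025), lower. With an estimated correlation these had adjusted p = 0.23, 0.28, 0.28, 0.23, 0.52 and 0.23. Slc1a2 kept its call only without control 7, control 10 or deprived 10, P2ry12 and Slc1a3 passed without control 7, and Gja1 without deprived 10. The unbound count was 1141 without control 7, 402 without control 8, 396 without deprived 10, 383 without deprived 7 and 247 without deprived 8. It was 294 without 17R and 21L, of which 268 were shared.

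The difference between the effects in bound and unbound RNA of the heterozygous line asked what was specific to microglia. No gene passed with edgeR (0 of 19275, 1904 at unadjusted p under 0.05), against 170 with DESeq2, 11 with limma-voom and 34 with the mouse as a replicate block. The edgeR count was 2 without bound control 2 and 60 without unbound control 9. As groups, microglia markers (median 0.28, adjusted p = 0.0098), cell cycle genes (0.27, 4.0e-05), stress and heat shock genes (0.30, 5.0e-04) and cytosolic ribosomal proteins (0.20, 6.6e-09) had a higher effect in bound than in unbound RNA. With an estimated correlation these had adjusted p = 0.73, 0.47, 0.35 and 0.64. The effect was also higher in bound RNA for engulfment and complement genes (median 0.16, adjusted p = 0.025) and actin linkers (0.13, 0.032), and lower for synaptic genes (-0.09, 0.0045) and mitochondrially encoded genes (-0.27, 0.0062) (adjusted p = 0.64, 0.47, 0.64 and 0.64 with an estimated correlation).

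In microglia without Cx3cr1, deprived and control libraries of the same 5 mice were compared to ask whether the response needs the receptor (n = 5 bound libraries per group). Tcf7l2 (ENSMUSG00000024985, chromosome 19, 55741820 to 55933654), a transcription factor that acts with beta-catenin in Wnt signalling, fell by 2.83 ± 0.35 (adjusted p = 0.015). Its level was 94.2 ± 48.7 CPM in control and 13.4 ± 1.41 CPM in deprived libraries (SD, n = 5 each). It was the 1 gene of 18324 past the threshold (edgeR, 690 at unadjusted p under 0.05, 11 with DESeq2, 1 with limma-voom, 2 with the mouse as a replicate block). Among microglial and glial genes, Cx3cr1 stood at -0.09 ± 0.31, Csf1r at 0.01 ± 0.33, P2ry12 at 0.05 ± 0.38, and Tmem119 at 0.02 ± 0.37. Gfap stood at 0.14 ± 0.16, Wnt5a at 0.05 ± 0.13 and Lef1 at -0.72 ± 0.31. Among the next smallest p-values were those of the neurofilament gene Nefh (-0.78 ± 0.13), Zfhx4 (-0.73 ± 0.15), Fign (-1.56 ± 0.32) and, higher, Dtx4 (0.33 ± 0.08) and Lhx2 (0.29 ± 0.08). None of 28 gene lists was called in bound RNA.

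Unbound RNA of the knockout line gave 7 genes of 18421, all lower (n = 5 per group, 874 at unadjusted p under 0.05, 35 with DESeq2, 1 with limma-voom). Tcf7l2 fell by 2.89 ± 0.36 (adjusted p = 0.018). The inhibitor of differentiation Id4 (-0.71 ± 0.10), the RNA-binding protein Rbms3 (-0.51 ± 0.07), the actin-associated Synpo2 (-0.79 ± 0.12), the protein kinase C family member Prkch (-0.70 ± 0.10), the diacylglycerol kinase Dgkk (-0.92 ± 0.14) and the ATPase family member Fign (-2.08 ± 0.33, adjusted p = 0.047) fell too. Reactive astrocyte genes (median -0.19, adjusted p = 0.0012), mitochondrially encoded genes (-0.20, 0.0010) and engulfment and complement genes (-0.09, 0.0053) fell as groups without a called member. They had adjusted p = 0.87, 0.77 and 0.87 with an estimated correlation. Astrocyte markers (median -0.07, adjusted p = 0.023), immediate early genes (-0.09, 0.023), oligodendrocyte lineage markers (-0.08, 0.040) and cytokine and NF-kB genes (-0.12, 0.040) fell as well (adjusted p = 0.87, 0.76, 0.76 and 0.76 with an estimated correlation). With the mouse as a replicate block the calls of the oligodendrocyte and cytokine lists were lost (adjusted p = 0.051 and 0.057). Cytosolic ribosomal proteins rose with 26 of 28 above 0 and a median of 0.04 (adjusted p = 0.016, and adjusted p = 0.92 with an estimated correlation). Wnt5a stood at -0.14 ± 0.16, Gfap at -0.09 ± 0.14 and Lef1 at -0.72 ± 0.20. The difference between the fractions gave 0 genes with edgeR (335 at unadjusted p under 0.05), DESeq2 and limma-voom, and stood at 0.057 ± 0.52 for Tcf7l2. Cytosolic ribosomal proteins differed between the fractions as a group (median -0.11, adjusted p = 8.9e-05, and adjusted p = 0.99 with an estimated correlation).

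Control pieces of the knockout line spread widely in Tcf7l2, from 23.6 to 158 CPM bound, while deprived pieces lay between 11.6 and 15.1, and the call was lost under several alternatives. In bound RNA it was lost with limma-voom (adjusted p = 0.26), without mice 7 and 18 (0.60), and without any of the 5 deprived libraries or control 18 or 19, when the count was 0. Without control 22, 2 genes passed. In unbound RNA the count was 0 without deprived 7, 12, 19 or 22 or control 7, 1 without control 12 or 18, 2 without deprived 18, 3 without control 19 and 22 without control 22. It was 1 without mice 7 and 18 and 3 with the mouse as a replicate block.

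Regional genes, in the same lists written after the results were seen, had medians below 0 in the knockout line, again given without a test. In bound RNA these were -0.51 for the thalamic list, which holds Tcf7l2, -0.96 for septum and midline, -0.51 for the striatal list, -0.10 for the hippocampal list and -0.12 for non-primary cortical areas. In unbound RNA they were -0.53, -0.91, -0.36, -0.09 and -0.06. Crym of the last list was not lower in deprived pieces, at 46.1 CPM in control and 47.0 in deprived bound libraries and 62.2 and 67.1 in unbound ones.

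**Figure D4:**
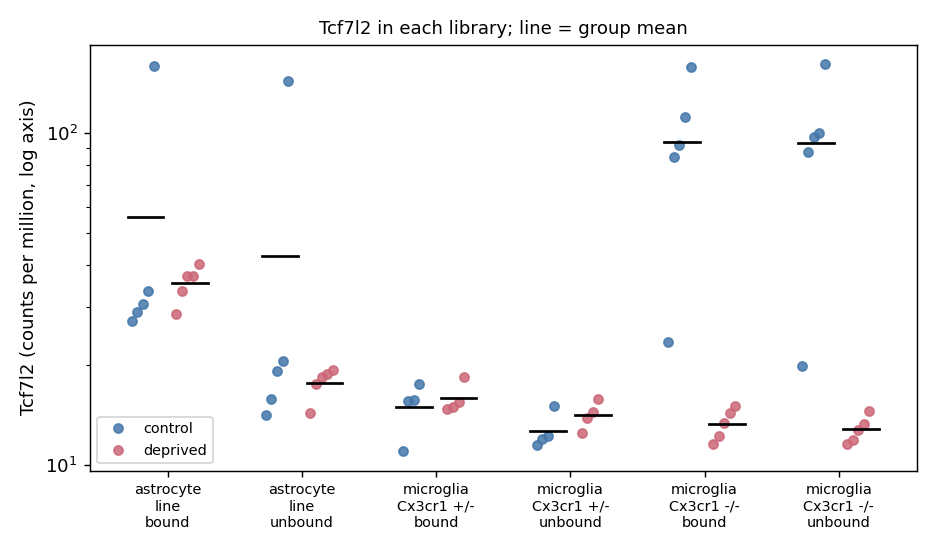
Tcf7l2 in CPM (log axis) in each library by line, fraction and whisker treatment, with points for libraries and a line for each group mean. Bound control libraries of the knockout line lie between 23.6 and 158 and deprived ones between 11.6 and 15.1, and control 3 of the astrocyte line stands at 159.

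Whether the deprivation effect in bound RNA differed between genotypes was tested as the effect in the knockout line minus that in the heterozygous line (n = 5 and 4 libraries per group). The effect was lower in the knockout line for Tcf7l2 (-2.91 ± 0.43, adjusted p = 0.023), Zic1 (-3.71 ± 0.62), the synaptic adhesion gene Slitrk6 (-2.50 ± 0.42), Sowaha (-1.53 ± 0.26) and the RNA methyltransferase Trmt2b (-1.11 ± 0.18). It was higher for the Notch regulator Dtx4 (0.66 ± 0.11), the ephrin Efna5 (0.92 ± 0.16), Mef2c (0.96 ± 0.17), Cxxc4, an inhibitor of Wnt signalling (0.88 ± 0.16), and B3galt2 (0.68 ± 0.13). In all 100 of 19601 genes passed, 38 higher and 62 lower (edgeR, 3380 at unadjusted p under 0.05, 734 with DESeq2, 160 with limma-voom). Unbound RNA moved likewise for leading genes. From control to deprived, Zic1 went from 7.29 to 33.3 CPM in the heterozygous and from 56.9 to 20.4 in the knockout line, and Tcf7l2 from 12.7 to 14.2 and from 93.4 to 12.8. Different tissue in the pieces of the lines can therefore not be told apart from a response of microglia. Interferon response genes had a lower effect in the knockout line, with 15 of 16 below 0, and a median of -0.69. Of these, 8 passed the test adjusted over the list alone but 0 over all genes. For their difference camera gave adjusted p = 8.4e-06, and adjusted p = 0.50 with an estimated correlation. The effect was lower, too, for reactive astrocyte genes (median -0.84, adjusted p = 3.2e-05), inflammatory cytokine and NF-kB genes (-0.75, 5.1e-05) and microglia markers (-0.52, 0.0099). These had adjusted p = 0.50, 0.50 and 0.60 with an estimated correlation. So it was for astrocyte markers (median -0.42, adjusted p = 1.9e-04), cytosolic ribosomal proteins (-0.22, 9.8e-05), engulfment and complement genes (-0.38, 0.0016), microglial activation genes (-0.43, 0.0031), border macrophage and leukocyte markers (-1.45, 0.0091) and cell cycle genes (-0.34, 0.015), and it was higher for synaptic genes (0.20, 0.0084). With an estimated correlation these had adjusted p = 0.50, 0.57, 0.57, 0.57, 0.57, 0.60 and 0.57. The difference stood at -0.60 ± 0.21 for Gfap, -0.51 ± 0.19 for Wnt5a and -1.31 ± 0.42 for Lef1, which did not pass. By side letter 2 genes passed, 4 with the mouse as a replicate block as well, and 5 without 17R and 21L. The count was 0 without heterozygous control 4 or deprived 2, 2 without deprived 1, and 4, 18 and 264 without controls 3, 2 and 1 of that line. It was 1, 21 and 441 without knockout controls 12, 18 and 7, and 46, 177 and 201 without knockout deprived 7, 22 and 19.

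Enrichment in bound over unbound RNA was also compared between genotypes, where a batch difference shared by both fractions cancels. No gene passed with edgeR (0 of 20676, 712 at unadjusted p under 0.05), DESeq2 or limma-voom, and 1 passed without knockout bound deprived 19. Cx3cr1 stood at 0.49 ± 0.30. Cell cycle genes were less enriched in the knockout line, with all 19 below 0 and a median of -0.23 (adjusted p = 6.6e-09, and adjusted p = 0.76 with an estimated correlation). So were microglia markers, with a median of -0.15 (adjusted p = 0.0054, and adjusted p = 0.99 with an estimated correlation). The enrichment difference lay below 0 too for cytosolic ribosomal proteins (median -0.11, adjusted p = 2.6e-08), microglial activation genes (-0.20, 7.9e-04), interferon response genes (-0.11, 0.012) and cytokine and NF-kB genes (-0.18, 0.028), while that of mitochondrially encoded genes (0.15, 9.9e-04) lay above 0. With an estimated correlation these had adjusted p = 0.76, 0.76, 0.99, 0.77 and 0.76.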

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

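Every test of an explanation and every count of splits given here was chosen after the result it bears on had been seen. The test of the difference between genotypes was fixed beforehand.

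Grouped by title, the heterozygous line differed between deprived and control libraries in 1850 genes in bound and 678 in unbound RNA. The grouping by side letter, which does not conflict with the labelled lesion of the right side, gave 0 in either fraction. Brain region lists moved with the groups by title. Prox1 of hippocampal granule cells stood at 41.7 ± 4.78 CPM in control and 104 ± 13.8 in deprived unbound libraries (SD, n = 4 each). An accident of mice 17 and 21 as animals was not excluded. Of 964 genes picked from the bound libraries of these mice alone, 92.7% lay on the same side between the sides of mice 14 and 15. In unbound RNA 93.5% of 124 genes picked did. Most of these genes thus differed the same way in mice 14 and 15. Genes that move together are not independent, so the shares rest on these other mice alone, too few to exclude such an accident. A candidate explanation is that the dissected pieces held different neighbouring tissue. A score was taken over the called genes without members of the regional lists. Its range, lowest to highest library, was set against the difference of the heterozygous group means, 1.38. That range was 87.0% in the deprived (SD 0.58) and 47.7% in the control unbound group of the knockout line. In the astrocyte line it was 16.3% in the deprived and 62.7% in the control unbound group, where control 4 stands at -3.73 against -3.02 to -2.87. A range is wider than a spread of means, and these values show that pieces vary in such genes without naming the source. An effect of the whisker lesion cannot be told apart from different neighbouring tissue, because a tissue difference that coincided with the groups would give the same calls. Of the genes called in unbound RNA, 15.3% of 672 lay on the same side in unbound RNA of the knockout line, which also differs in genotype, and 73.3% of 643 did in the astrocyte line. No other split of the 35 gave as many genes, with at most 7 in bound and 12 in unbound RNA and 0 in the 23 that also parted 2 mice, but splits that keep mice 17 and 21 whole on opposite sides are too few for a share under 5%.

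Tcf7l2 fell in the deprived pieces of the knockout line by 2.83 ± 0.35 bound and by 2.89 ± 0.36 unbound. The fall differed between fractions by 0.057 ± 0.52, under the bound of 1 set for a change inside the tagged microglia alone. Unbound RNA also held microglial RNA (Csf1r at 4.00 CPM), so such a change can appear in both fractions and this difference by itself cannot judge it. Tcf7l2 stood at 94.2 CPM in bound and 93.4 CPM in unbound control libraries, so its RNA was not concentrated in the bound fraction there. Microglial genes were, with Csf1r at 26.4 and 3.97 CPM and P2ry12 at 13.6 and 2.83 CPM in the same groups. These levels argue against a change of Tcf7l2 inside the tagged microglia alone. Thalamic tissue in control pieces may be the source, but this stays open: the 9 members of the thalamus list that were not called had a median of -0.16 in unbound RNA, with Lhx9 lowest at -1.63 ± 0.57, and thalamic tissue and an effect on a few genes cannot be told apart. An effect of the lesion that needs no knockout was not seen in the heterozygous line, but its values cannot decide. There Tcf7l2 stood at 0.20 ± 0.10 in unbound RNA, with every library between 11.5 and 15.9 CPM. Deprived unbound libraries of the knockout line lay between 11.6 and 14.6 CPM. The heterozygous controls already stood at that level, so a fall from the knockout control level could not appear in them. In unbound RNA of the astrocyte line Tcf7l2 stood at -1.26 ± 0.51, but this value rests on control 3 at 144 CPM. The other controls of that line lay between 14.2 and 20.6 CPM and its deprived libraries between 14.4 and 19.4 CPM. In bound RNA 5 of 100 splits gave as many genes as the real 1, the highest 56 in a split that kept mice 7 and 12 whole, which points to a structure of the samples, so chance cannot be excluded there, while in unbound RNA 3 of 100 reached the real 7, the highest 13, and splits parting all 5 mice, at most 0 in either fraction, are too few for a share under 5%.

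The pulldown enriched many of the same genes in all 3 lines. That only RNA of the tagged cell type was bound is argued against in the microglial lines by the levels of neuronal RNA. Bound libraries held the neuron markers Snap25 at 937 and 937 CPM and Tubb3 at 349 and 317 in the heterozygous and knockout lines. The microglial gene Csf1r stood at 33.5 and 26.5 CPM there. For the astrocyte line the question stays open. A first test asked whether the median of the neuron markers lay below 0, and it was no higher than -0.17 in any line. Of 20 neuron markers, 5, 6 and 6 passed as enriched and 12, 9 and 9 as depleted in the astrocyte, heterozygous and knockout lines. A median below 0 shows depletion relative to unbound RNA and not absence, so this first test cannot decide. A test added after it gave a rank correlation of enrichment over genes of 0.530 between the astrocyte and heterozygous lines. Mitochondrial ribosomal RNAs and the median neuron marker were depleted in both lines. Shared depletion can give such a correlation with RNA of the tagged cells alone, so the second test cannot decide. Transcript length was argued against as the whole cause by a rank correlation of 0.0915 in the astrocyte line, barely under the bound of 0.1 set for it, while the other lines gave 0.407 and 0.438. GC content may contribute and cannot be told apart from other properties of these transcripts, with rank correlations of 0.332, 0.242 and 0.204 in the astrocyte, heterozygous and knockout lines.

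Other splits were counted for each comparison. By splits of single pieces, chance can be excluded for enrichment in the astrocyte line (10838 genes, 1 of 40 splits as large, highest other 2119), the heterozygous line (12069, 1 of 40, 7866) and the knockout line (12187, 1 of 40, 6532). These splits swapped the fractions piece by piece and did not keep both pieces of a mouse together. In the microglial lines the splits that do are too few for a share under 5%, and the astrocyte labels name no animals. For the deprivation effects of the heterozygous line (1 of 35 in each fraction) the splits that keep its mice as they stand are too few for a share under 5%. In unbound RNA of the knockout line (7, 3 of 100, 13) the splits that part all 5 mice are too few for a share under 5%, with 0 as the highest of the 11 drawn. For the difference of the deprivation effect between genotypes (100, 1 of 60, 9) the 17 drawn splits that part as many mice gave at most 0 and are too few as well. For the level difference between genotypes (11, 1 of 40, 0) the splits of libraries did not keep mice whole. With the libraries of each mouse summed, 10 of 100 splits of the 9 mice gave as many genes as the real 1, the highest 14, so chance cannot be excluded for that count, and a split with 14 points to a structure of the samples. With 0 genes in the real split, all splits were as large in bound (100 of 100, highest 6) and unbound (100 of 100, highest 30) RNA of the astrocyte line. So they were in the differences between fractions of the astrocyte (60 of 60, highest 1), heterozygous (35 of 35, highest 1) and knockout lines (60 of 60, highest 2), and in the enrichment difference between genotypes (40 of 40, highest 0).

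The deprivation effect in bound RNA differed between the knockout and heterozygous lines for 100 genes. Of the 10 named, the difference was -2.91 for Tcf7l2, -1.11 for Trmt2b, -3.71 for Zic1, -2.50 for Slitrk6, and -1.53 for Sowaha. It was 0.66 for Dtx4, 0.92 for Efna5, 0.96 for Mef2c, 0.88 for Cxxc4 and 0.68 for B3galt2.

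Of 120 group values over 10 measures, 9 had a library far from the rest of its group, where chance gives about 1 in 20. Crym stood at 80.4 CPM in unbound control 12 of the knockout line, against 55.2 to 60.7 in the others. Cx3cr1 stood at 0.121 CPM in unbound deprived 19 of the knockout line, against 0.0451 to 0.0663. Gfap stood at 102 CPM in bound control 4 of the astrocyte line, against 146 to 163. Prox1 stood at 149 CPM in bound control 18 of the knockout line, against 118 to 125. Mitochondrial ribosomal RNA took 1.40% of counts in bound deprived 1 of the astrocyte line, against 1.70 to 1.80%. It took 3.53% in bound control 18 of the knockout line, against 1.56 to 1.80%. Tcf7l2 stood at 159 CPM in bound and 144 in unbound control 3 of the astrocyte line, against 27.2 to 33.5 and 14.2 to 20.6. Tmem119 stood at 7.50 CPM in bound deprived 3 of the heterozygous line, against 5.17 to 5.40.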

How the results depend on the processing

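Alternatives for the genotype difference in bound RNA, and the fits that summed, isolated or left out mice or pieces (mice 14 and 15, mice 17 and 21, mice 7 and 18, astrocyte control pieces 3 and 4), were chosen after seeing the data. All others were planned. The cause of each change below was not tested unless stated. DESeq2 size factors kept every count of genes within 1.5 times. Over the alternatives, values of named genes that had passed kept their call and sign in 10877 of 11728 cases. They lost the call in 850 and changed sign in 1 (Ccl5 in bound RNA of the heterozygous line, -0.15 by side letter). Values of named genes that had not passed stayed so in all but 408 of 14990 cases, with the other sign in 370.

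Without the filter on low counts, where more genes of few counts enter the fit, the number of genes past the threshold was 85 and 143 in bound and unbound RNA of the astrocyte line and 15 for their difference. It was 1459 in unbound RNA of the heterozygous line and 118 for its difference, and 28 and 52 in the knockout line and 1 for their difference. Between genotypes it was 576 for the effect difference, 1 for the enrichment difference and 143 for the level difference. DESeq2 gave 7 in bound RNA of the astrocyte line, and 1176 in unbound RNA and 170 for the difference between fractions of the heterozygous line. It gave 11 and 35 in the knockout line, and 734 and 71 for the effect and level differences between genotypes. Limma-voom gave 11 for the difference between fractions of the heterozygous line, 1 in unbound RNA of the knockout line, and 160 and 27 for the effect and level differences between genotypes.

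Grouping the heterozygous libraries by side letter gave 0 genes in either fraction and 2 for the effect difference between genotypes. With the mouse as a replicate block as well it gave 0, 0 and 4, since this exchanges the groups of 17R and 21L. Leaving out 17R and 21L, which also leaves fewer samples, gave 741, 294 and 5. Summing the libraries of mice 17 and 21 gave 951 genes in bound RNA, and summing the libraries of each mouse gave 1 for the level difference between genotypes, with fewer samples. The mouse as a replicate block gave 34 genes for the difference between fractions of the heterozygous line, and 2 and 3 in bound and unbound RNA of the knockout line. The replicate number of the titles as a block gave 2202 and 748 genes in bound and unbound RNA of the heterozygous line, and 0 and 0 in the astrocyte line. A block by number, mouse or piece moved no other count of genes or lists past 1.5 times, though lists called in unbound RNA of the knockout line went from 8 to 6. Astrocyte libraries of the same number correlated above 0.1, over genes after group means were removed, in 1 of 5 bound and 4 of 5 unbound cases. Of the 5 controls, 1 bound and 2 unbound correlated best with the deprived library of their own number. In unbound RNA of the knockout line sex as a covariate gave 2, all 4 groups in the fit 1, and leaving out mice 7 and 18, with fewer samples, 1, against 0 in bound RNA.

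Leaving out 1 library at a time gave 0 to 0 genes in bound and unbound RNA and their difference in the astrocyte line and for the difference in the knockout line. It gave 938 to 2089 and 247 to 1141 in bound and unbound RNA of the heterozygous line and 0 to 60 for their difference, and 0 to 2 and 0 to 22 in the knockout line. Between genotypes it gave 0 to 441 for the effect difference, 0 to 1 for the enrichment difference and 7 to 31 for the level difference. Enrichment gave 10642 to 11030, 11720 to 12094 and 11872 to 12314 genes in the astrocyte, heterozygous and knockout lines.

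With an estimated correlation, the number of gene lists called fell from 4 to 0, 7 to 0, 11 to 1 and 3 to 0 in bound RNA, unbound RNA, enrichment and difference of the astrocyte line. It fell from 14 to 0, 16 to 0, 8 to 1 and 8 to 0 in the heterozygous line, and from 8 to 0, 5 to 0 and 1 to 0 in unbound RNA, enrichment and difference of the knockout line. For effect, enrichment and level between genotypes it fell from 11 to 0, 7 to 0 and 14 to 2. Depth limits Cx3cr1 in unbound libraries of the knockout line, with 2 to 8 counts each.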

Other observations

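Some genes of Wnt signalling were more abundant in astrocyte-bound than in unbound RNA, a comparison fixed beforehand (n = 10 libraries per fraction). The ligands Wnt5a (1.10 ± 0.10), Wnt7a (0.81 ± 0.09) and Wnt7b (0.55 ± 0.08), the receptor Fzd2 (1.65 ± 0.15), and the Wnt targets Axin2 (0.63 ± 0.07) and Lef1 (0.82 ± 0.13) were enriched. Wnt4 (0.17 ± 0.11) and Wls (-0.26 ± 0.12) were not past the threshold. Canonical Wnt targets were enriched as a group, 15 of 19 called with a median of 0.54 (adjusted p = 0.0025, and adjusted p = 0.20 with an estimated correlation). Genes of Wnt release were depleted, with a median of -0.24 (adjusted p = 0.034, and adjusted p = 0.23 with an estimated correlation). The lists of Wnt ligands, receptors and antagonists were not called (medians 0.35, 0.41 and 0.42, adjusted p = 0.26, 0.17 and 0.26). Synaptogenic and matrix factors were enriched with a median of 0.55 and 14 of 17 called. They included the matrix proteoglycans Bcan (1.72 ± 0.06) and Ncan (1.46 ± 0.06), the matrix glycoprotein Tnc (1.70 ± 0.06) and Chrdl1 (0.95 ± 0.06). Camera gave these factors adjusted p = 9.3e-06, and adjusted p = 0.23 with an estimated correlation. Genes of glutamate and potassium handling had a median of 0.83, with the potassium channel Kcnj10 at 1.22 ± 0.05 (adjusted p = 3.7e-08, and adjusted p = 0.23 with an estimated correlation). Cell cycle genes had a median of 0.43, with the proliferation marker Mki67 at 1.05 ± 0.05 (adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation).

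In microglia-bound RNA, genes of inflammatory cytokines and NF-kB were enriched in both lines, with medians of 1.72 in the heterozygous and 1.55 in the knockout line (adjusted p = 0.41 and adjusted p = 0.51 with an estimated correlation). So were engulfment and complement genes, with medians of 0.94 and 0.88 (adjusted p = 0.067 and adjusted p = 0.51 with an estimated correlation). Cytosolic ribosomal proteins were depleted, 28 of 28 in the heterozygous and 28 of 28 in the knockout line, with medians of -0.71 and -0.86 (adjusted p = 0.26 and adjusted p = 0.22 with an estimated correlation). The GFP transcript, counted in the heterozygous table, stood at 6.73 ± 1.55 CPM in bound and 0.747 ± 0.171 in unbound libraries (SD, n = 8 each). By group it stood at 5.49 ± 1.11 CPM in control (4.60 to 7.08) and 7.98 ± 0.542 in deprived bound libraries (7.40 to 8.71), and at 0.712 ± 0.225 and 0.782 ± 0.121 in control and deprived unbound libraries (SD, n = 4 each).

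Vessel genes rose as groups in unbound RNA of deprived cortex in the heterozygous line, without a called member. Mural and fibroblast markers had a median of 0.36 and all 11 above 0 (adjusted p = 0.0010, and adjusted p = 0.42 with an estimated correlation), and endothelial markers a median of 0.30 (adjusted p = 0.0099, and adjusted p = 0.48 with an estimated correlation). Across genes the deprivation changes of the heterozygous and knockout lines had r = -0.19 in bound and r = -0.31 in unbound RNA. Those of the heterozygous and astrocyte lines had r = 0.08 in bound and r = 0.18 in unbound RNA, where genes are not independent replicates.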
